A study of Mus musculus with 24 samples.

How the data were processed

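RNA was measured in mouse GT1-7 cells in 24 libraries, 12 from a fractionation experiment (wt and Mkrn3ox cells, total and cytoplasmic RNA) and 12 from an RNA immunoprecipitation experiment (6 µg of GFP or GFP-Mkrn3 plasmid for 24 h, GFP-trap IP and 5% input), with 3 libraries in each of 8 groups. Per the labels' protocols, reads were trimmed with cutadapt, aligned to mm10 with STAR and counted per gene with HTSeq. The versions, the gene annotation, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. The deposited tables hold raw counts, as whole numbers in 57010 gene rows each, of which 52029 have an identifier found in the reference name table and 1606 have no gene name. All 24 libraries and all rows were used, and groups were taken from the labels.

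Each experiment was fitted separately with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, group means with no covariate, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a call at an adjusted p under 0.05. The 9 contrasts were Mkrn3ox against wt in total RNA and in cytoplasmic RNA, the difference between these, cytoplasm against total RNA in wt cells, GFP-Mkrn3 against GFP in the inputs and in the IPs, IP against input for each plasmid, and the difference between the last pair, called enrichment beyond GFP. The contrasts and their tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, except for the tests and alternatives said to be chosen afterwards. The test of the order within overlapping gene pairs and that of Xist in the stable line were chosen after the data were seen. Genes named are a preset list (Mkrn3, Gnrh1, Mkrn1, Mkrn2, Nptx1, Pabpc1, Pabpc4, Pcsk1, Pcsk2, Cpe, Pam and Qpct where tested), the 8 called genes with the largest change in each direction, or 4 for the other contrasts, with a mean of at least 20 counts, and up to 4 members of each called list. Of the genes this rule selects, 3 are not reported here. Levels are CPM values of edgeR on the TMM scale.

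The 20 gene lists covered the makorin family, reported Mkrn3 substrates, GnRH neuron regulators, prohormone processing, cytosolic ribosomal proteins, translation factors, stress granules and P-bodies, mitochondrial mRNAs, the nuclear-encoded respiratory chain, nuclear-retained RNAs, endoplasmic reticulum stress, interferon response, G2 and mitosis, p53 targets, cholesterol synthesis, immediate early genes, neuronal cytoskeleton and synapse, imprinted genes, and markers of astrocytes and oligodendrocytes and of fibroblasts, endothelium and immune cells. Lists with at least 5 tested members, 16 in the fractionation contrasts and 19 in the RIP contrasts, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated per list and with fry. Overlaps used Fisher's exact test in scipy 1.17.1 with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Overlap and neighbour relations came from GRCm38 gene positions, with a window of 5 kb and intervals of rank correlations from 1000 bootstrap draws. Levels in the GFP-Mkrn3 IP were also fitted, over 11306 genes, as a mixture of its own input and the GFP IP with 1 shared proportion.

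Alternatives were DESeq2 (1.42.0) size factors or library size alone as scaling, no filter on low counts, a filter at a mean of 20 counts, the DESeq2 test, the compared groups alone in the fit, the replicate number as a block across groups or within a line or plasmid, and leaving out each library in turn. After the data were seen, a fit without the rows of mt-Nd6 and Grtp1 and the alternatives for genes above their own input were added. Every split of 3 against 3 libraries was refitted, and 100 drawn splits for the differences of differences.

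The fits were tested on simulated data with 200 changed genes. In the fractionation design they recovered 8.96% of 2-fold and 47% of 4-fold changes in total RNA, 11.9% and 45.5% in the cytoplasm and 5.97% and 21.2% in the ratio, and 0% of 1.5-fold changes in each. In the RIP design they recovered 50.7%, 79.1% and 93.9% of 1.5-, 2- and 4-fold changes in the inputs and 17.9%, 49.3% and 77.3% for the enrichment beyond GFP, with 1 to 7 false calls. A count of 0 over a group was given a floor of 3 counts, and intervals of shares are exact (Clopper-Pearson). Intervals and floors cover counting error only.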

Results

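Mkrn3 encodes makorin ring finger protein 3, a zinc-finger protein with a RING domain whose loss in people is known to bring on early puberty. The series title names RNA binding by this protein, and the translation and cellular placement of the Gnrh1 precursor, as the subject. GT1-7 is an immortalised mouse hypothalamic neuronal line that makes gonadotropin-releasing hormone. The fractionation experiment measured total and cytoplasmic RNA of unmodified cells (wt) and of a line with stable GFP-Mkrn3 (Mkrn3ox) by CEL-seq2, a method that reads 3' ends, with 3 libraries in each of 4 groups. The RIP experiment, RNA immunoprecipitation on beads that bind GFP, used cells given a GFP or a GFP-Mkrn3 plasmid for 24 h. It measured the pulled-down RNA (IP) and 5% of the lysate (input), with 3 libraries in each of 4 groups. The deposited values were counts per gene. Each fractionation library held 374386 to 759271 counts over 8309 to 11284 detected genes. The totals were 577589 to 759271 in wt total, 513166 to 589792 in Mkrn3ox total, 412605 to 582256 in wt cytoplasm and 374386 to 465260 in Mkrn3ox cytoplasm. Each RIP library held 6254703 to 14575652 counts over 15566 to 20599 genes. Levels are given in CPM, counts scaled to a common library size, ± SD over 3 libraries, and changes as log2 fold changes. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg correction unless another test is named. The labels do not say whether libraries of a group came from separate cultures, so these p-values measure only the spread between libraries, which may be technical.

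Libraries of a group resembled each other less in the fractionation experiment than in the RIP experiment. The biological coefficient of variation was 0.384 over 5033 tested genes in the former and 0.115 over 13052 in the latter. Of the RIP pairs GFP-Mkrn3 IP libraries 2 and 3 were least alike. Their Pearson's r of log2 CPM was 0.963, against 0.98 to 0.993 for the other pairs within a RIP group. In the fractionation table mt-Nd6, the mitochondrial mRNA transcribed from the strand opposite to the others, took 36877 to 135260 counts per library, 25.3 to 69.1 times the sum of the other mitochondrial mRNAs. In the RIP inputs that ratio was 0.265 to 0.471. Of the 13 mitochondrial mRNAs 7 were tested in each experiment. The other 6 (mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l) held 0 counts in the fractionation table and 0 to 5 per RIP library. Tsix, the antisense gene of Xist, held 1623 to 2266 counts in the wt total libraries, where Xist held 139 to 159, while the RIP inputs held 0 to 4 counts of Tsix and 434 to 554 of Xist. Among 665 overlapping gene pairs with a 10-fold or larger difference in the RIP inputs, 231 (34.7%, exact 95% interval 31.1 to 38.5) stood in the inverted order in the fractionation table, against 445 of 6706 adjacent pairs without overlap (6.64%, 6.05 to 7.26). The strand setting behind the counts is not given in the sources used here, so a fractionation value below is the value of the named row in the deposited table. Of 80 named rows, 8 (the 7 mitochondrial rows and Magea9) could not be placed in the reference, 51 had another gene overlapping them or within 5 kb, and 24 had a neighbour more abundant in the RIP inputs. Among these were Tsix with Xist, Mettl7b with Itga7, St3gal6 with Dcbld2, Ap3m1 with Vcl, Iah1 with Adam17, Igsf10 and Gpr171 with Med12l, Ercc2 with Ppp1r13l and Cd302 with Marchf7. For Gnrh1 the most abundant gene within 5 kb, Dock5, was less abundant than Gnrh1 in the inputs (193 against 317 CPM).

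**Figure D1:**
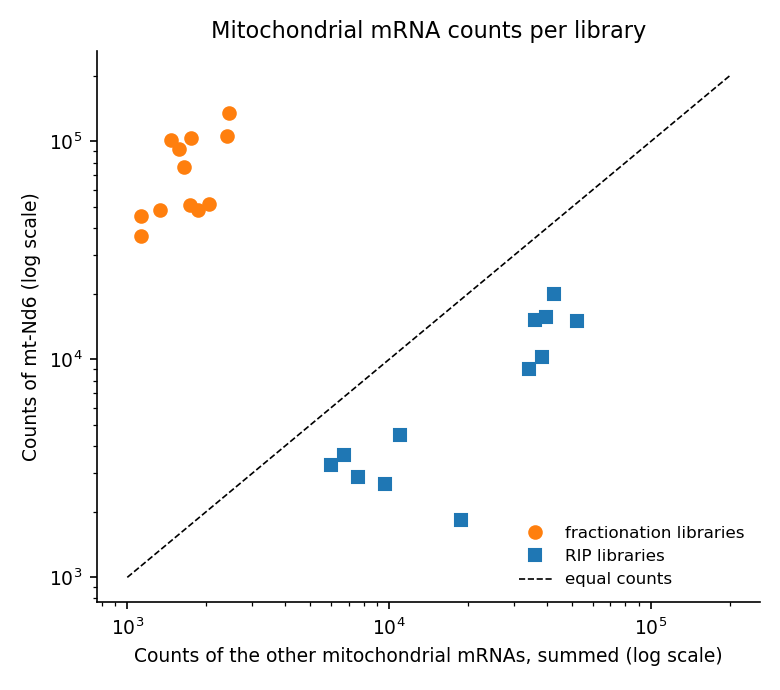
Counts of mt-Nd6 against the summed counts of the other mitochondrial mRNAs in each of the 24 libraries, on log axes, with a line of equal counts. In the fractionation libraries mt-Nd6 lies 25.3 to 69.1 times above the others, and in the RIP inputs it lies at 0.265 to 0.471 of them.

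The cytoplasmic and total RNA of wt cells were compared to describe what the fractionation separated. Nuclear-retained non-coding RNAs were lower in the cytoplasm. Malat1, a nuclear speckle RNA, was at 6.99 ± 6.06 CPM in the cytoplasm and 135 ± 24.2 in total RNA (log2 fold change −4.17, SE 0.614, adjusted p = 0.000165, n = 3 per group). Xist, the RNA that coats the silenced X chromosome, was at 4.61 against 242 CPM (−5.57). Kcnq1ot1, the antisense RNA of an imprinted domain, stood at 0.862 against 51.0 CPM and Firre, a chromatin-associated RNA, at 0.911 against 23.2. Cd302 was at least 64.4-fold lower in the cytoplasm, Rmnd1 at least 49.7-fold, Cd46 at least 34.8-fold and Nr6a1os at least 23.4-fold, each against a floor of 3 counts over the 3 libraries where it had none. Egr1, an immediate early transcription factor, was higher in the cytoplasm (81.1 against 5.18 CPM, 3.90, adjusted p = 0.000893). So were Ptn, the secreted growth factor pleiotrophin (53.3 against 4.09 CPM, 3.60), Igfbp5 (246 against 34.2 CPM, 2.84) and Ap3s2 (60.7 against 8.86 CPM, 2.70). Total RNA includes the cytoplasm, so rises of this size need not come from the fractionation. Their cause was not tested.

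Among lists fixed before the data were examined, 4 of 6 nuclear-retained RNAs were lower in the wt cytoplasm, also 4 adjusted over the list alone (camera adjusted p = 1.13e-09, and adjusted p = 0.00246 with an estimated correlation). Of 7 mitochondrially encoded mRNAs, mt-Nd6 alone was higher over all genes (0.68, adjusted p = 0.000798) and 5 were adjusted over the list alone (median 0.682, camera adjusted p = 0.000282, adjusted p = 0.0448 with an estimated correlation). Prohormone processing genes had a median of 0.509 (camera adjusted p = 0.0467, adjusted p = 0.166 with an estimated correlation). Of these 8 genes 0 passed the edgeR test, also 0 adjusted over the list alone, while 805 of all 5033 genes had an unadjusted p under 0.05. Immediate early genes had a median of 0.558, with Egr1 alone of 10 higher over all genes and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.18 with an estimated correlation). In all, 190 of 5033 genes differed, 31 higher and 159 lower in the cytoplasm. Scaling by library size gave 16 and 230, with a median of all genes of −0.219 against 0.0148. The higher genes were 50 without wt total library 1, 17 without wt total library 3 and 52 with the DESeq2 test. The call of Igfbp5 was lost with the DESeq2 test (adjusted p = 0.207) and without wt cytoplasm library 3 (0.055), that of Firre in 5 of 6 leave-outs (up to 0.163) and that of Ap3s2 in all 6 (0.0605 to 0.14). Each of the last pair was also lost in 2 other alternatives (up to 0.0935 and 0.0868).

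The Mkrn3ox line and wt cells were compared in total RNA to ask which RNAs differ between lines labelled as with and without stable GFP-Mkrn3. Ptn rose from 4.09 ± 1.11 to 610 ± 52.8 CPM (7.11, SE 0.35, adjusted p = 5.48e-12, n = 3 per group), and Uchl1, an abundant neuronal ubiquitin hydrolase, from 2.54 to 84.0 CPM (4.88). Zfhx4, a homeobox factor of neural tissue, was at least 106-fold higher and Cd28, a T-cell co-receptor, at least 64.9-fold higher in Mkrn3ox, against a floor of 3 counts over the 3 libraries. Lrrc55, a potassium channel subunit, stood at 77.9 against 0.447 CPM, Scn7a at 107 against 1.15, the adhesion receptor Adgrl3 at 94.5 against 1.15 and Zfhx2 at 68.2 against 1.65. Xist was at least 136-fold lower, Gpr171 at least 54.3-fold, Igsf10 at least 49.1-fold, Magea9 at least 46.2-fold, Arap2 at least 24.5-fold and B4galt6 at least 21.7-fold lower in Mkrn3ox. The row of Tsix went from 2990 ± 60.5 to 13.8 CPM (−7.75, adjusted p = 3.08e-12), that of Gask1b from 146 to 0.614 CPM. Pam, the enzyme that amidates peptide hormones such as GnRH, rose from 1180 ± 193 to 2850 ± 108 CPM (1.27, SE 0.162, adjusted p = 1.66e-05).

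Of 13 cholesterol synthesis genes 2 were higher and 1 lower in Mkrn3ox total RNA, and 8 and 1 adjusted over the list alone (median 1.32, camera adjusted p = 0.0157, adjusted p = 0.175 with an estimated correlation). Insig1, a sterol sensor of the pathway, rose from 189 to 548 CPM (1.52, adjusted p = 0.000685). Hmgcs1, an early enzyme of it, rose from 63.8 to 183 CPM (1.51, adjusted p = 0.00834), and Fdft1, named after its value was seen, fell (−0.96). Rpl22 (2.03), Rack1 (0.85) and Rps21 (1.14) rose among cytosolic ribosomal protein genes, whose median was 0.481. These were 3 of 46 over all genes, and 2 were higher adjusted over the list alone (camera adjusted p = 0.00157, adjusted p = 0.11 with an estimated correlation). Nuclear-retained RNAs had a median of −0.726, with Xist alone of 6 past the test over all genes and also 1 adjusted over the list alone (camera adjusted p = 0.00157, adjusted p = 0.0786 with an estimated correlation). The neuronal cytoskeleton and synapse list had a median of 0.718 (camera adjusted p = 0.0537). Gnrh1 was at 90.0 ± 43.1 CPM in Mkrn3ox and 77.3 ± 9.07 in wt (0.22, SE 0.445, adjusted p = 0.857), a difference below the spread between libraries. Mkrn2, a makorin of the same family (−0.05, adjusted p = 0.946), Pabpc1, the cytoplasmic poly(A)-binding protein (0.62, adjusted p = 0.406) and Cpe, which trims prohormones (−3.05, adjusted p = 0.108), were also not past the test. Mkrn3 itself held 0 counts in all 6 total libraries and 0 to 5 in the cytoplasmic ones (1, 0 and 5 in Mkrn3ox), too few to test. Whether the construct holds the 3' end that CEL-seq2 reads is not given in the sources used here, nor is the strand setting, so these counts show neither its expression nor a lack of it.

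In total RNA 372 of 5033 genes differed, 179 higher and 193 lower in Mkrn3ox, and scaling by library size gave 252 and 163. The count was 238 without wt total library 3 and 234, 236 and 235 without Mkrn3ox total library 1, 2 and 3, with 112 to 119 higher, and 117 were higher without wt total library 2. The calls of Rps21, Rack1 and Rpl22 were lost in 6, 5 and 3 of 6 leave-outs (adjusted p up to 0.211, 0.145 and 0.145), and that of Hmgcs1 without Mkrn3ox total library 1 (1.22, adjusted p = 0.0755). In other alternatives Rps21 was lost in 3 (up to 0.204) and Rack1 with no filter (0.0657).

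In cytoplasmic RNA the Mkrn3ox line had less of several secretory and immediate early transcripts than wt cells. Cpd, a carboxypeptidase of the secretory path, went from 339 ± 26.7 to 98.4 ± 48.4 CPM (−1.78, SE 0.311, adjusted p = 0.000614, n = 3 per group). Rab3a, a GTPase of secretory vesicles, went from 595 to 265 CPM (−1.17, adjusted p = 0.000701), Prcp from 135 to 47.7 CPM (−1.49, adjusted p = 0.0236), and Cpe was at least 13.4-fold lower. These 4 of 8 prohormone processing genes, also 4 adjusted over the list alone, came with a median of −1.15 (camera adjusted p = 0.00426, adjusted p = 0.0871 with an estimated correlation). Fosl2 (197 to 48.9 CPM, −2.01), Jund (193 to 81.9 CPM, −1.24), Egr1 (81.1 to 14.3 CPM, −2.49) and Dusp1 (69.9 to 24.1 CPM, −1.52) fell. These were 4 of 10 immediate early genes over all genes, also 4 adjusted over the list alone, with a median of −0.447 (camera adjusted p = 0.0351, adjusted p = 0.189 with an estimated correlation). Of 7 mitochondrial mRNAs, mt-Nd6 (255000 to 105000 CPM, −1.29, adjusted p = 1.28e-07) and mt-Nd5 (1220 to 519 CPM, −1.23) fell. The list had 2 lower members also adjusted over the list alone and a median of −0.698 (camera adjusted p = 0.00563, adjusted p = 0.118 with an estimated correlation). Ribosomal protein genes had a median of 0.639. Rplp2 (43.7 to 173 CPM, 1.95, adjusted p = 0.00213), Rpl11 (8.41 to 51.9 CPM, 2.61) and Rps21 (1.13) rose, and Rpl32 (−1.14), named after its value was seen, fell. These were 4 of 46, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.00426, adjusted p = 0.128 with an estimated correlation).

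The named genes with the largest changes in the cytoplasm were near absent from 1 of the lines. Uchl1 rose from 3.60 to 173 CPM (5.60, SE 0.686, adjusted p = 1.05e-05). Ercc2, a DNA repair helicase, stood at 141 against 1.82 CPM, Lrrc55 at 79.6 against 0.862 and the checkpoint kinase gene Chek2 at 51.1 against 2.73 CPM. Magea8, Ppp2r2c and Spdya were at least 22.6-, 21.0- and 20.3-fold higher, against the same kind of floor. Pdpn, the membrane glycoprotein podoplanin, was at least 106-fold lower in Mkrn3ox. Pde6h went from 663 ± 116 to 7.47 ± 8.96 CPM (−6.49, adjusted p = 2.6e-09). So did Rtraf from 410 to 3.94, Med12l from 248 to 0.848, the imprinted factor Plagl1 from 149 to 0.697, Magea9 from 115 to 0.848 and Tmem252 from 97.0 to 0.848 CPM. Gnrh1 was at 146 ± 13 CPM in Mkrn3ox and 109 ± 77.3 in wt, with 11 to 86 counts per wt library (0.41, SE 0.444, adjusted p = 0.629). Pam (0.17, adjusted p = 0.585), Pabpc1 (0.61, adjusted p = 0.341) and Mkrn2 (−0.08, adjusted p = 0.903) were not past the test. In all 526 of 5033 genes differed, 217 higher and 309 lower. The higher genes were 137 and 132 without wt cytoplasm library 1 and 2 and 140 without Mkrn3ox cytoplasm library 1. Between the calls in total and cytoplasmic RNA, 84 higher genes were shared against 7.72 by chance (odds ratio 31.4). For lower genes 120 were shared against 11.8 (odds ratio 40.5, Fisher's exact test, p = 4.54e-104). Total RNA includes the cytoplasmic RNA and both contrasts compare the same lines in 1 fit, so a large overlap was given by the design. Genes are not independent replicates either, so these values are a description only.

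**Figure D2:**
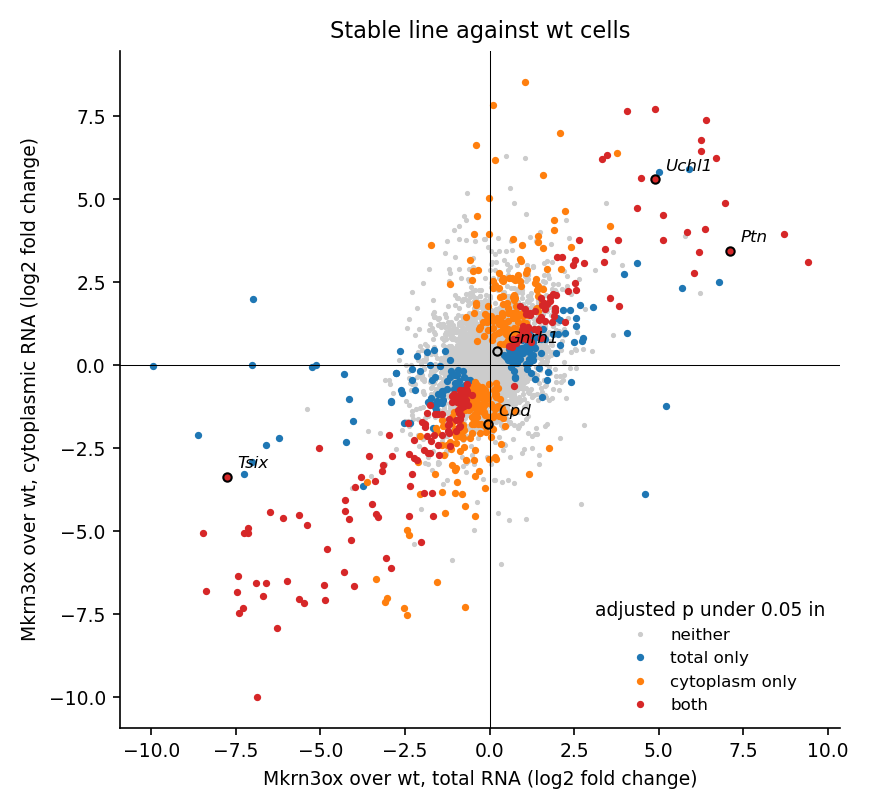
Log2 fold changes of Mkrn3ox over wt cells in total and cytoplasmic RNA for each tested gene, with called and named genes marked. Ptn and Uchl1 lie high and Tsix lies low.

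Scaling the cytoplasmic libraries by library size gave 507 higher and 189 lower genes, a median of all genes of 0.375 against 0.0301, and left the median of the immediate early list at −0.103. Calls were lost when single libraries were left out for Rps21 (6 of 6 leave-outs, adjusted p up to 0.185), Prcp (4, up to 0.112), Rpl11 (4, up to 0.285) and Dusp1 (4, up to 0.117). The same held for Chek2 (3, up to 0.333), Egr1 (3, up to 0.0578) and Jund (without library 3 of either cytoplasmic group, up to 0.0582). Other alternatives ended the calls of Rps21 (3, up to 0.202), Dusp1 (3, up to 0.111), Rpl11 (2, up to 0.0817), Prcp (1, 0.0744) and Jund (library size, 0.0553).

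The change in the cytoplasm-to-total ratio asks whether the placement of an RNA differs between the lines. Pam fell by 1.10 in this ratio (SE 0.227, adjusted p = 0.0367, n = 3 per group): its total level was higher in Mkrn3ox while its cytoplasmic level was 1780 against 1580 CPM. Ptn fell by 3.66 (adjusted p = 0.000497), since in wt cells its cytoplasmic level exceeded its total level and in Mkrn3ox the levels were 584 and 610 CPM. Total RNA includes the cytoplasm, so this fall need not be a change of placement. Ap3m1, an adaptor of vesicle sorting (−1.88, SE 0.25, adjusted p = 0.000497), Cdh11, a cadherin (−2.14, adjusted p = 0.00434), and Iah1 (−2.10, adjusted p = 0.00789) were lower as well. So were Mettl7b (−1.48, adjusted p = 0.00454) and St3gal6, a sialyltransferase (−1.35, adjusted p = 0.011). Tsix (4.39, adjusted p = 0.00379), Perm1 (5.05, adjusted p = 0.0329), Xist and Timp4 were higher, the last pair with 0 to 5 counts in the Mkrn3ox libraries, so that their fitted changes are no bound. The rows of Ap3m1, Iah1, Mettl7b, St3gal6, Tsix, Perm1 and Timp4 have a neighbour more abundant in the RIP inputs. Mettl7b and St3gal6 held 0 CPM in the RIP inputs, against 11002 and 11187 counts over the fractionation libraries. These rows may therefore not measure the named genes.

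Prohormone processing genes had a median ratio change of −1.36, with 1 of 8 lower over all genes, Pam, and 3 lower adjusted over the list alone (camera adjusted p = 0.000187, adjusted p = 0.0305 with an estimated correlation). The values of Cpd (−1.74, adjusted p = 0.0993), Prcp (−1.61, adjusted p = 0.317) and Qpctl (−1.61, adjusted p = 0.482) did not pass. Mitochondrial mRNAs had a median of −0.56 (camera adjusted p = 0.00513, adjusted p = 0.104 with an estimated correlation) and immediate early genes of −0.634 ( camera adjusted p = 0.0381, adjusted p = 0.162 with an estimated correlation). These lists had 0 members past the edgeR test over all genes, and 1 of 7 and 2 of 10 lower adjusted over the list alone. In wt cells the prohormone, mitochondrial and immediate early lists were higher in the cytoplasm than in total RNA (medians 0.509, 0.682 and 0.558). The ratio change subtracts this wt difference, taken from the same libraries. Total RNA includes the cytoplasm, so the falls of these lists need not be changes of placement in Mkrn3ox. Gnrh1 changed by 0.19 (SE 0.63, adjusted p = 0.947), and Mkrn2 (−0.04), Pabpc1 (−0.01) and Cpe (−3.98, adjusted p = 0.553) were not past the test. In all 11 of 5033 genes differed, 4 higher and 7 lower (8 and 6 with scaling by library size, where the median was 0.267 against 0.0188), 485 had an unadjusted p under 0.05, and DESeq2 called 50. The count was 35 without wt total library 1 and 43 with no filter on low counts. The calls of Pam, Perm1, St3gal6 and Xist were lost in 8, 6, 2 and 1 of 12 leave-outs (adjusted p up to 0.13, 0.102, 0.0666 and 0.0929), for St3gal6 without wt total library 3 or Mkrn3ox total library 1 and for Xist without Mkrn3ox cytoplasm library 2. Other alternatives ended those of Pam (3, up to 0.107) and Perm1 (2, up to 0.069).

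In the RIP inputs the transient plasmid raised Mkrn3 (ENSMUSG00000070527, chromosome 7, 62417593 to 62420153, GRCm38) from 6.20 ± 2.33 CPM with GFP to 3690 ± 74.2 with GFP-Mkrn3 (9.25, SE 0.169, adjusted p = 4.41e-18, n = 3 per group). Apart from Mkrn3, the row Gm25395 alone passed the test, lower with GFP-Mkrn3, and was named after its value was seen. Its call was lost in all 6 leave-outs, with the replicate block and with only the compared groups in the fit. Gnrh1 was at 319 ± 19.4 CPM with GFP-Mkrn3 and 313 ± 27.5 with GFP (0.03, SE 0.0898, adjusted p = 0.984). Values for Mkrn1 (−0.08), Mkrn2 (−0.07), Pabpc1 (0.08), Pabpc4 (0.06), Pam (−0.06), Cpe (0.03), Pcsk2 (0.01) and Nptx1 (0.76), with adjusted p from 0.93 to 0.999, did not pass. As a group, 33 genes of endoplasmic reticulum stress had a median of −0.117 with GFP-Mkrn3 (camera adjusted p = 0.000627, adjusted p = 0.0268 with an estimated correlation), for example the chaperone Hspa5 (−0.26), its partner Hyou1 (−0.22) and Trib3 (−0.39). Mitochondrial mRNAs had a median of 0.402 (camera adjusted p = 0.00214, adjusted p = 0.451 with an estimated correlation) and 32 genes of G2 and mitosis 0.0875 (camera adjusted p = 0.0158, adjusted p = 0.229 with an estimated correlation). No member of these 3 lists passed the edgeR test, over all genes or adjusted over the list alone, and across 13052 genes 734 had an unadjusted p under 0.05. The 2 calls became 6 with DESeq2, 34 with no filter on low counts, 4 with only the compared groups in the fit, and 1 without GFP input library 2 or any of the 3 GFP-Mkrn3 input libraries.

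The GFP pull-down is the background against which GFP-Mkrn3 is read. With GFP alone, Gnrh1 fell from 313 ± 27.5 CPM in the input to 83.8 ± 7.99 in the IP (−1.90, SE 0.0953, adjusted p = 4.21e-11, n = 3 per group). Kcnq1ot1 (139 CPM in the IP, 3.36, adjusted p = 8.26e-11), Xist (2.87) and Neat1, a paraspeckle RNA (1.73), rose over input. So did Phxr4 (4.22), Itgb1bp2 (3.34) Eid3 (3.13) and Ftx (1.35). The respiratory chain genes Uqcr10 (−3.23, adjusted p = 1.09e-11), Cox7a2 (−3.02) and Cox7b (−2.80), and the ribosomal protein genes Rpl41 (−2.90) and Rps12 (−2.47) fell. So did mt-Rnr2, a mitochondrial ribosomal RNA (−4.34), F12 (−4.38) and Rny1, a small cytoplasmic RNA (−7.19). Rn7s2 was at least 21.6-fold lower than in the input, against a floor of 3 counts over the 3 libraries. Over all genes 76 of 83 ribosomal protein genes were lower and 0 higher, the same counts adjusted over the list alone (median −1.31, camera adjusted p = 8.08e-45, adjusted p = 0.00183 with an estimated correlation). Of 77 nuclear-encoded respiratory chain genes 69 were lower and 3, Ndufs1 (0.92), Sdha (0.72) and Atp5a1 (0.28), named after their values were seen, were higher. The counts were 70 and 3 adjusted over the list alone (median −1.55, camera adjusted p = 7.22e-36, adjusted p = 0.0011 with an estimated correlation). All 7 tested mitochondrial mRNAs were lower, also 7 adjusted over the list alone (median −2.18, camera adjusted p = 5.55e-09, adjusted p = 0.0743 with an estimated correlation). Of 11 nuclear-retained RNAs 6 were higher, 7 adjusted over the list alone (median 1.22, camera adjusted p = 2.8e-06, adjusted p = 0.107 with an estimated correlation). Of 7 fibroblast, endothelial and immune markers 4 were higher, Fn1 (0.78), Kdr (0.92), Col1a1 (0.85) and Col1a2 (0.59). These were also 4 adjusted over the list alone (median 0.593, camera adjusted p = 0.0385, adjusted p = 0.122 with an estimated correlation). In all 6565 of 13052 genes differed, 3274 higher and 3291 lower, or 2554 and 3952 with scaling by library size, where the median was −0.115 against −0.0045. Of the preset genes Mkrn2 (−0.68) and Pabpc1 (−0.28) were lower and Mkrn1 (0.346), Pabpc4 (0.272), Pam (0.256) and Cpe (0.195) higher. The calls of these last 4 were lost in 2, 2, 3 and 5 of 6 leave-outs (adjusted p up to 0.135, 0.0745, 0.0708 and 0.186) and with scaling by library size (0.12, 0.137, 0.114 and 0.37).

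The changes from input to IP were less spread with GFP-Mkrn3 than with GFP, with an SD of 0.495 against 0.724 over 11306 genes. Mkrn3 RNA was at 9540 ± 414 CPM in the GFP-Mkrn3 IP and 3690 ± 74.2 in its input (1.37, SE 0.111, adjusted p = 8.94e-08, n = 3 per group). Kcnq1ot1 (2.86), Xist (2.43), Ftx (1.66), Neat1 (1.38), Phxr4 (5.44), Itgb1bp2 (4.80), Pcdhgb5 (3.73) and Gpr21 (3.37) were above input. The mitochondrial RNAs mt-Co1 (−2.48, adjusted p = 2.6e-10), mt-Cytb (−2.83), mt-Nd6 (−3.20) and mt-Rnr2 (−6.48), and the small RNAs Rny1 (−5.44) and Rny3 (−4.68), were below it. Ribosomal protein genes were lower for 39 of 83 and higher for 2, Rps29 (1.12) and Rpl36 (1.27). Here 45 were lower and 4 higher adjusted over the list alone (median −0.347, camera adjusted p = 3.76e-13, adjusted p = 0.046 with an estimated correlation). Respiratory chain genes were lower for 41 of 77 and higher for 2, Atp5g2 (1.04) and Ndufs7 (0.84). There 45 were lower and 2 higher adjusted over the list alone (median −0.402, camera adjusted p = 3.76e-13, adjusted p = 0.0201 with an estimated correlation). Mitochondrial mRNAs were lower for all 7 tested, also 7 adjusted over the list alone (median −2.48, camera adjusted p = 1.11e-29, adjusted p = 0.00906 with an estimated correlation). Nuclear-retained RNAs were higher for 5 of 11 and lower for Tug1 (−0.35), 7 and 1 adjusted over the list alone (median 1.21, camera adjusted p = 1.11e-08, adjusted p = 0.046 with an estimated correlation). Rpl36, Atp5g2, Ndufs7 and Tug1 were named after their values were seen. Immediate early genes were higher for 9 of 23, for example Junb (0.98), Egr2 (0.96), Myc (0.66) and Klf10 (0.58). They were higher for 11 adjusted over the list alone (median 0.28, camera adjusted p = 0.0079, adjusted p = 0.37 with an estimated correlation). Gnrh1 was lower than in the input (−0.61, SE 0.0901, adjusted p = 0.000108). Mkrn1 (−0.16), Mkrn2 (−0.29), Pabpc1 (0.13), Pabpc4 (−0.02), Pcsk2 (−0.04), Cpe (−0.02), Pam (−0.08) and Nptx1 (0.06) did not pass the test. In all 3487 of 13052 genes differed, 1812 higher and 1675 lower, or 2599 and 1263 with scaling by library size, where the median was 0.113 against 0.0285. The higher genes were 1195 without GFP-Mkrn3 input library 2.

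**Figure D3:**
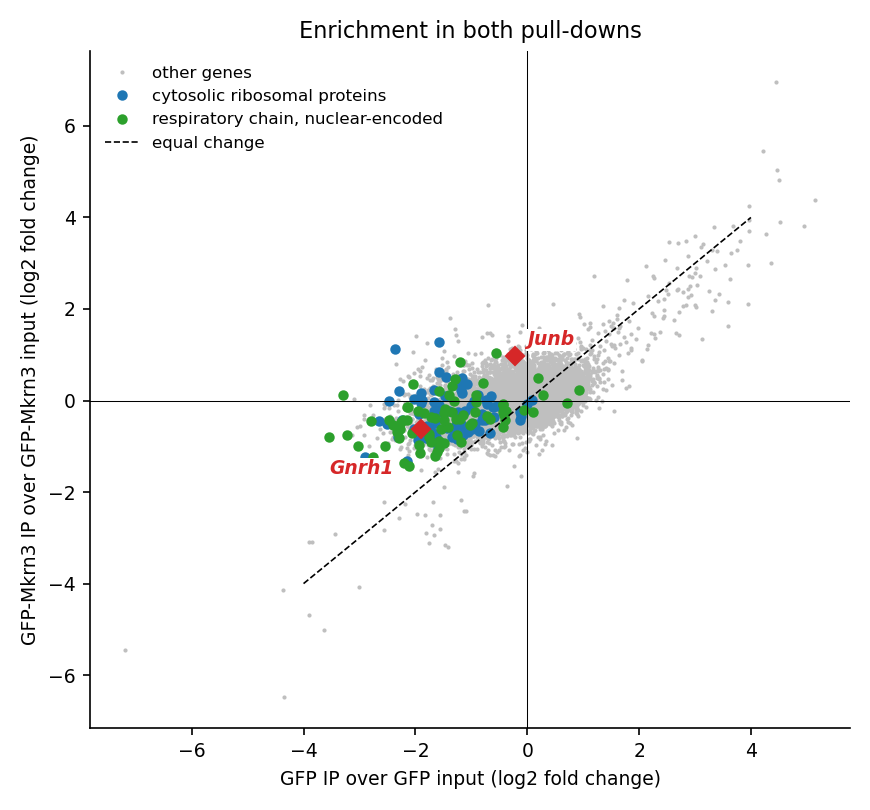
Log2 fold change of IP over input with GFP-Mkrn3 against that with GFP for each gene. The slope over 11306 genes is 0.397 (Pearson's r = 0.58 across genes, which are not independent replicates).

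Enrichment with GFP-Mkrn3 beyond GFP was tested as the difference between the changes from input to IP. Gnrh1 (ENSMUSG00000015812, chromosome 14, 67745181 to 67749440, GRCm38) scored 1.29 (SE 0.13, adjusted p = 5.14e-06, n = 3 per group). Its level was 209 ± 11.7 CPM in the GFP-Mkrn3 IP, 319 ± 19.4 in its input, 83.8 ± 7.99 in the GFP IP and 313 ± 27.5 in the GFP input. The level in the GFP-Mkrn3 IP thus lay above the GFP IP (1.32, SE 0.0942, adjusted p = 2.68e-08) and below its own input. A mixture of input and GFP IP levels, with an input-like share of 0.6 fitted over 11306 genes, gave 224 CPM for Gnrh1 in the GFP-Mkrn3 IP. Mkrn3 scored 1.19 (adjusted p = 0.00116) and Pabpc1, a reported partner of Mkrn3, 0.41 (adjusted p = 0.00951). The plasmid raised Mkrn3 in the GFP-Mkrn3 cells, so its score sets largely plasmid RNA against the cells' own Mkrn3 RNA with GFP. It does not show binding of the cells' own Mkrn3 RNA. Pam (−0.34, adjusted p = 0.0396) and Mkrn1, a makorin known to bind RNA (−0.51, adjusted p = 0.0451), scored below 0. Mkrn2 (0.39, adjusted p = 0.107), Pabpc4 (−0.29, adjusted p = 0.0963), and Pcsk2 (−0.30, adjusted p = 0.203) did not pass. Nor did Cpe (−0.22, adjusted p = 0.176) and Nptx1 (−0.65, adjusted p = 0.658), whose product is a reported substrate of Mkrn3.

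**Figure D4:**
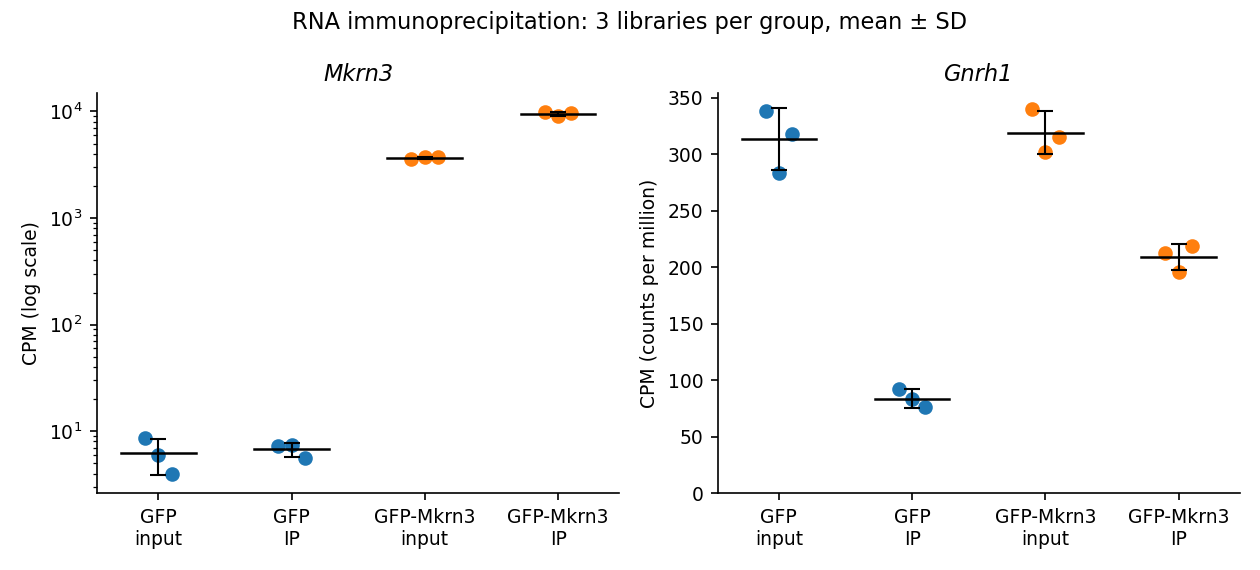
Levels of Mkrn3 and Gnrh1 in each library, in CPM, with group means and SD over 3 libraries. Gnrh1 lies at 83.8 CPM in the GFP IP, at 209 in the GFP-Mkrn3 IP and at 313 and 319 in the inputs.

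Respiratory chain and ribosomal protein genes, which GFP alone had depleted, scored high. Of 77 nuclear-encoded respiratory chain genes 51 were higher and 2 lower, Sdha (−0.77) and Ndufs1 (−0.69), named after their values were seen. The counts were 60 and 3 adjusted over the list alone (median 1.05, camera adjusted p = 1.01e-25, adjusted p = 0.00511 with an estimated correlation). The higher genes included Atp5md (2.75), Uqcr10 (2.48), Cox7b (2.35, SE 0.17, adjusted p = 1.28e-07) and Cox7a2 (2.04). Of 83 ribosomal protein genes 63 were higher and 0 lower, 69 and 0 adjusted over the list alone (median 0.993, camera adjusted p = 9.83e-33, adjusted p = 0.00663 with an estimated correlation). Examples were Rpl38 (2.07), Rps12 (1.99) and Rps28 (1.5). Of 23 immediate early genes 8 were higher, also 8 adjusted over the list alone (median 0.485, camera adjusted p = 0.0178, adjusted p = 0.422 with an estimated correlation). They included Junb (1.2), Jund (0.96), Myc (0.76) and Atf3 (0.71). The genes with the largest scores were Rps29 (3.48), Cox6a2 (3.43), Plvap (3.40), Crct1 (3.34), Il17d (3.31), Sh3bp1 (3.17), Coa6, a respiratory chain assembly factor (3.13), and Bri3 (3.05).

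The lists of cell division and RNA granule genes were called lower with the preset correlation and not with an estimated one. Of 32 genes of G2 and mitosis 13 were lower and 5 higher, 14 and 5 adjusted over the list alone (median −0.258, camera adjusted p = 0.0081, adjusted p = 0.106 with an estimated correlation). The lower genes included the kinetochore genes Cenpe (−1.0) and Cenpf (−0.98), Top2a (−0.86) and Kif11 (−0.82), and the higher genes were Ube2c (1.34), Birc5 (0.94), Cenpa (0.86), Ccnb2 (0.75) and Ckap2l (0.54). Of 39 stress granule and P-body genes 8 were lower and Pnrc1 (0.79) higher, 5 and 1 adjusted over the list alone (median −0.23, camera adjusted p = 0.0178, adjusted p = 0.334 with an estimated correlation). The lower genes included Tnrc6b (−0.72), G3bp2 (−0.55), G3bp1 (−0.40) and Cnot1 (−0.32). These 6 higher genes were named after their values were seen. Of 8 astrocyte and oligodendrocyte markers Pdgfra alone was lower (−0.77, adjusted p = 0.000238), also 1 adjusted over the list alone (median −0.527, camera adjusted p = 0.0362, adjusted p = 0.146 with an estimated correlation). The lowest scores were those of mt-Tp (−2.47), mt-Rnr2 (−2.14), the myosins Myh7 (−2.11) and Myh11 (−1.76), Notch3 (−1.93), Eid3 (−1.79), mt-Nd6 (−1.79) and the histone gene H4c1 (−1.68). Lists with no camera call for this score were translation factors (median 0.0182, 13 of 67 higher and 9 lower, adjusted p = 0.82), GnRH neuron regulators (0.239, 4 of 18 higher and 6 lower, adjusted p = 0.779) and reported Mkrn3 substrates (0.0305, 2 of 6 higher and 1 lower, adjusted p = 0.82). No call was made either for interferon response (0.0164, adjusted p = 0.405), p53 targets (−0.0574, adjusted p = 0.405), imprinted genes (−0.0244, adjusted p = 0.82) and neuronal cytoskeleton and synapse (−0.11, adjusted p = 0.199). The other 6 lists with no call were endoplasmic reticulum stress (0.253, 10 of 33 higher and 11 lower, adjusted p = 0.82), cholesterol synthesis (−0.183, 1 of 24 higher and 5 lower, adjusted p = 0.226), prohormone processing (−0.235, 2 of 18 higher and 3 lower, adjusted p = 0.352), mitochondrial mRNAs (−0.275, 2 of 7 lower, adjusted p = 0.14), nuclear-retained RNAs (−0.292, 1 of 11 lower, adjusted p = 0.213) and fibroblast, endothelial and immune markers (−0.261, 2 of 7 lower, adjusted p = 0.156). The makorin family had 3 members, too few to test.

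In all 3178 of 13052 genes differed from GFP, 1724 higher and 1454 lower, with 814 and 70 beyond 2-fold. The GFP-Mkrn3 IP was also simulated as a mixture of its input and the GFP IP alone, with the input-like share of 0.6. Over 10 such draws 1363 to 1446 genes scored as enriched beyond GFP, so most of a count like 1724 can arise without binding by Mkrn3. Of the 1724, 1655 were also higher in the GFP-Mkrn3 IP than in the GFP IP, 1493 (86.6%) were below input with GFP. Of them 335 (19.4%) were below their own GFP-Mkrn3 input like Gnrh1, and 235 (13.6%, exact 95% interval 12 to 15.3) were above it. That last group, with a median of 0.67 over its input, held Junb and Mkrn3, the latter as RNA raised by the plasmid. It also held Osgin1 (2.09 over its input), Klf10, Ulk1 and Nfyc, of which Osgin1, Ulk1 and Nfyc were named after their values were seen. Of the 1454, 1195 (82.2%) were above input with GFP. The direct comparison of the IPs gave 4907 genes, 2661 higher and 2246 lower with GFP-Mkrn3. These included Mkrn3 (10.44, adjusted p = 8.49e-19), Rps29 (3.28), Rps26 (1.86) and Ndufa4 (1.81) higher and Mir6236 (−2.99), H4c1 (−1.52), mt-Rnr1 (−1.48) and H4c6 (−1.44) lower. Il17d (3.16) and the preset genes Pabpc1 (0.49) and Mkrn2 (0.323) were also higher, and Mkrn1 (−0.59), Pam (−0.39) and Pabpc4 (−0.234) lower. Of the 22 named and called genes of this contrast, 4 lost the call in a leave-out and 3 in another alternative. Calls were lost for mt-Rnr1 without GFP IP library 2 or 3 (adjusted p = 0.0655 and 0.0987) and for Il17d without GFP-Mkrn3 IP library 2 (0.0561). Those of Mkrn2 and Pabpc4 were lost in 6 and 4 of 6 leave-outs (up to 0.146 and 0.147) and in 2 and 4 other alternatives (up to 0.0653 and 0.659). In it 69 of 83 ribosomal protein genes were higher and 3 lower, 70 and 3 adjusted over the list alone (median 0.898, camera adjusted p = 8.67e-31, adjusted p = 0.00988 with an estimated correlation). For respiratory chain genes 64 of 77 were higher and 3 lower, 65 and 4 adjusted over the list alone (median 1.03, camera adjusted p = 1.47e-26, adjusted p = 0.00625 with an estimated correlation). The lower genes, named after their values were seen, were Rpl5 (−0.53), Rpl3 (−0.36), Rpl7l1 (−0.28), Ndufs1 (−0.75), Sdha (−0.73) and Ndufv1 (−0.42).

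Scaling by library size gave 2845 higher and 603 lower genes for the enrichment beyond GFP, with a median of 0.233 against 0.0386, and 4104 and 1154 for the IPs, with 0.208 against 0.0299. It left medians of −0.0632 for G2 and mitosis and −0.0367 for stress granule genes, and ended the calls of Mkrn1 (adjusted p = 0.192), Pam (0.336), Cnot1 (0.354), G3bp1 (0.132) and G3bp2 (0.0535). The 235 genes above their own input became 64 without GFP-Mkrn3 IP library 2, 788 without IP library 3, 113 without IP library 1, 100 and 89 without GFP-Mkrn3 input library 1 and 2, and 154 without GFP input library 2. Calls were lost in leave-outs for Mkrn1 (10 of 12, adjusted p up to 0.12), Pam (9), Eid3 (8), Sh3bp1, Myh7 and Cnot1 (6 each), Il17d (5), mt-Tp (4), Notch3 (without GFP IP library 1 or 2) and Plvap (without GFP input library 2), with adjusted p up to 0.169. Other alternatives also ended the calls of Eid3, Il17d, Sh3bp1 and Myh7 (up to 0.0818).

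RNAs enriched with GFP-Mkrn3 were compared with those changed in the stable line, over 4406 genes tested in both experiments, of which 587 were enriched. Of 174 genes higher in Mkrn3ox cytoplasm 37 were enriched, against 23.2 by chance (odds ratio 1.81, two-sided Fisher's exact test, p = 0.00291, adjusted over 6 tests 0.0175). Genes are not independent replicates, so the p-values of these overlaps are a description only. The open strand question of the fractionation rows also applies to this match of rows. For genes lower in the cytoplasm, changed in total RNA or changed in the ratio, shared numbers ran from 0 to 29 with adjusted p from 0.947 to 1.0. With calls at an adjusted p of 0.01 the cytoplasmic overlap was 7 genes against 5.07 by chance (adjusted p = 1.0). With a mean of at least 20 counts in both experiments it was 28 genes against 16.9 (odds ratio 1.94, Fisher's exact test, adjusted p = 0.0265). The changes in Mkrn3ox total RNA and in the transient inputs had a correlation near 0 across the same genes, which are not independent replicates (Pearson's r = −0.0267, Spearman's rho = −0.029, bootstrap 95% interval −0.0577 to −9.62e-05). Neither of the 2 genes called in the inputs was tested in both experiments. With no called input change among the compared genes, a correlation near 0 cannot tell whether stable and transient effects differ.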

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

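The tests of the order within overlapping gene pairs and of Xist in the stable line were chosen only after the result was seen, and the others were planned. Differences between lines or plasmids were tested by an interaction term in edgeR, which gave 11 genes for the cytoplasm-to-total ratio and 3178 for the enrichment beyond GFP. In the ratio the named genes were Xist (9.93), Timp4 (9.01), Perm1 (5.05), Tsix (4.39), Ptn (−3.66), Cdh11 (−2.14), Iah1 (−2.10), Ap3m1 (−1.88), Mettl7b (−1.48), St3gal6 (−1.35) and Pam (−1.10). In the enrichment beyond GFP the genes with the largest changes were Rps29 (3.48), Cox6a2 (3.43), Plvap (3.40), Crct1 (3.34), Il17d (3.31), Sh3bp1 (3.17), Coa6 (3.13) and Bri3 (3.05), and mt-Tp (−2.47), mt-Rnr2 (−2.14), Myh7 (−2.11), Notch3 (−1.93), Eid3 (−1.79), mt-Nd6 (−1.79), Myh11 (−1.76) and H4c1 (−1.68). Preset genes there were Gnrh1 (1.29), Mkrn3 (1.19), Pabpc1 (0.41), Pam (−0.34) and Mkrn1 (−0.51). Members of called lists were Rpl38 (2.07), Rps12 (1.99), Rps28 (1.5), Atp5md (2.75), Uqcr10 (2.48), Cox7b (2.35), Cox7a2 (2.04), Junb (1.2), Jund (0.96), Myc (0.76), Atf3 (0.71), Cenpe (−1.0), Cenpf (−0.98), Top2a (−0.86), Kif11 (−0.82), Pdgfra (−0.77), Tnrc6b (−0.72), G3bp2 (−0.55), G3bp1 (−0.40) and Cnot1 (−0.32).

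In the fractionation table mt-Nd6 lay 25.3 to 69.1 times above the other mitochondrial mRNAs, against 0.265 to 0.471 in the RIP inputs. A shift of rows against gene names is argued against, since the best shift lowered the correlation between the tables (change in rho −0.525). Counts assigned on the strand opposite to the transcripts remain a candidate explanation, since 34.7% of overlapping pairs with unequal input levels stood in inverted order against 6.64% of adjacent pairs (odds ratio 7.49, Fisher's exact test, p = 1.08e-85). The planned test compared, over 3398 overlapping genes, the rank correlation with the neighbour's input level (0.414) and with the own level (0.627), and its difference of −0.212 (bootstrap 95% interval −0.25 to −0.174) met the outcome set against this explanation, but that outcome was wrongly set for this design: overlaps were read from gene spans with neither strand nor exon positions, so a neighbour need not lie on the opposite strand or share exons. The test of inverted order used the same spans and has the same limit. Over 16713 protein-coding genes without an overlapping gene, the rank correlation with the own input level was 0.855. The planned outcome thus went against the explanation, but because of this limit, recognised only after that outcome was set, the test cannot tell it apart from counting on the transcripts' own strand. No biological explanation was tested, and the doubt stays open for the fractionation values.

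For the enrichment beyond GFP, the library GFP-Mkrn3 IP 2 as its source is argued against, since 78.4% of the enriched genes were still called without it. Input-like RNA in the GFP-Mkrn3 pull-down is a candidate explanation for the score of Gnrh1: a mixture with an input-like share of 0.6 predicted 224 CPM where 209 were measured, and its residual of −0.0974 lay at percentile 55.4 of 1000 genes of similar level. As the whole cause for all enriched genes it is argued against by the planned bound of 5% with all libraries in the fit, since 13.6% (exact 95% interval 12 to 15.3) lay above their own input. The share was 6.7% to 34.3% in the alternatives except that without GFP-Mkrn3 IP library 2, which gave 4.43% (3.43 to 5.62). Without that library the bound was not exceeded, so this result depends on it. The intervals take genes as independent, which they are not. In 10 simulated draws of the mixture alone, with no library left out, 1363 to 1446 genes scored as enriched. Of these 4 to 19, at most 1.39%, lay above their own input. The draws gave each GFP-Mkrn3 IP library the same input-like share, so they do not cover a difference in share between these libraries. The same mixture left a median residual of 0.0252 for ribosomal protein genes and −0.0593 for respiratory chain genes. For immediate early genes it was 0.334, with 0.943 for Junb, and Rps29 had 1.65. For the enriched genes not above their own input an input-like share stays open, and for those above it the answer depends on GFP-Mkrn3 IP library 2. Binding by Mkrn3, the biological difference the design names, stays open as untested.

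The stable line differed from wt cells in 372 genes in total RNA, and the transient inputs in 2. Divergence of the stable line other than through Mkrn3 is a candidate explanation, since Xist was at least 136-fold lower in Mkrn3ox over a floor of 3 counts, while it did not pass the test between the inputs (63.9 against 56.9 CPM, 0.17, edgeR adjusted p = 0.933). The opposite-strand doubt touches the rows of Xist and Tsix, which both fell in total RNA. Stable GFP-Mkrn3 expression, the difference the design names, stays open as untested, and the labels give 1 stable line, so that line and construct are confounded.

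Chance as the source of the counts was examined with other splits of the libraries. For the enrichment beyond GFP 2 of 100 splits gave as many genes as the real 3178. The 12 splits that kept the plasmids of the IPs gave 2368 to 3203 genes, the highest other being 3203. The 88 that mixed the IPs gave 0, so that the count says nothing about the grouping of the inputs. The IPs by themselves make 10 splits of 3 against 3, too few for a share under 0.05. Chance is therefore not excluded for their grouping by this count. For the ratio 7 of 100 splits gave at least the real 11 genes, so that chance cannot be excluded by this count, and the highest other gave 823, many times the real count. Each of the 6 others kept the lines in the cytoplasm and exchanged most or all of the libraries in total RNA, so that they carry the difference between the lines and point to a structure of the samples by line, while the 88 splits that mixed the cytoplasmic libraries gave 0 to 8. For the other 7 contrasts 3 against 3 libraries make 10 splits, too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes, with 372 genes in total RNA, 526 in cytoplasmic RNA, 190 between wt fractions, 4907 between IPs, 3487 and 6565 for IP against input with GFP-Mkrn3 and GFP, and 2 between inputs, and the highest other gave 0 in each.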

How the results depend on the processing

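The alternatives for genes above their own input and the fits without the mt-Nd6 and Grtp1 rows were chosen after the data were seen. Single named genes kept direction and side of the threshold in 2016 of 2214 leave-outs and in 2107 of 2211 other alternatives, and 33 and 14 reversed, all of genes not past the test. The 9 counts of called genes, higher and lower summed, stayed within 1.5 times under each alternative, with these exceptions. Leaving out single libraries gave 234 to 306 genes in total RNA, 8 to 35 for the ratio and 1 to 3 in the inputs. With no filter the ratio gave 43 and the inputs 34, with DESeq2 50 and 6, and the inputs gave 4 with the compared groups alone. Of 159 list tests 35 were called, 14 with an estimated correlation, 76 with fry, which asks another question, and 36 with the replicate block. The overlap with the stable line was 0 of 6 tests at an adjusted p of 0.01 against 1. With a mean of at least 20 counts in both experiments that 1 was kept (Fisher's exact test, adjusted p = 0.0265). Of 235 enriched genes above their own input there were 567 with library size as scaling, 389 with no filter, 146 with the block within plasmid and 64 to 788 on leaving out single libraries. With the replicate number as a block the counts were 336 in total RNA, 475 in the cytoplasm, 9 for the ratio, 153 for wt fractions, 3195 beyond GFP, 4889 for the IPs, 3511 and 6588 for IP against input with GFP-Mkrn3 and GFP, and 2 in the inputs; with the block within line or plasmid they were 13, 158, 2642, 3001 and 6218 for the ratio, wt fractions, enrichment beyond GFP and the pair of IP against input contrasts. Residuals of libraries with the same number correlated at −0.26 to 0.43, and at −0.26 to 0.05 between IP and input of a plasmid. Of 12 libraries each, 7 in the RIP and 2 in the fractionation experiment correlated best with their own number. These values cannot show whether the numbers pair the libraries. Without mt-Nd6 and Grtp1 the counts were 369, 524, 11 and 188 for total RNA, cytoplasm, ratio and wt fractions. Reversed log2 values were, with library size as scaling, Mkrn2 0.067 (total), 0.265 (cytoplasm) and 0.198 (ratio), Pabpc1 0.266 (ratio), Pabpc4 0.063, Pcsk2 0.044, Cpe 0.063 and Pam 0.001 (GFP-Mkrn3 IP against input) and Pcsk2 −0.003 (inputs). With a mean of 20 counts they were Mkrn2 0.028 (cytoplasm) and 0.084 (ratio) and Pabpc1 0.118 (ratio), and with DESeq2 Pabpc1 0.01 (size factors) and 0.009 (test). Leave-outs ranged for Gnrh1 from −0.265 to 0.426 (total), −0.045 to 1.019 (cytoplasm), −0.262 to 0.802 (ratio), −0.123 to 0.942 (wt fractions) and −0.037 to 0.088 (inputs), for Mkrn2 from −0.211 to 0.047, −0.224 to 0.032, −0.173 to 0.11 and −0.166 to 0.112 (total, cytoplasm, ratio, inputs), and for Pabpc1 from −0.386 to 0.315 (ratio). They ranged for Nptx1 from −0.369 to 0.409 (IPs) and −0.407 to 0.35 (GFP-Mkrn3 IP against input), for Pabpc4 from −0.071 to 0.019, Pcsk2 −0.081 to 0.034 and Cpe −0.045 to 0.006 (same contrast), for Mkrn3 from −0.077 to 0.446 (GFP IP against input), and in the inputs for Pcsk2 from −0.063 to 0.078 and Cpe from −0.007 to 0.119. The cause was not tested. On simulated data 8.96% of 2-fold changes in total RNA were recovered, against 79.1% in the RIP inputs, and depth (374386 to 759271 against 6254703 to 14575652 counts) and spread between libraries were not varied apart.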

Other observations

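No test was run for this part. The composition of the libraries differed between the experiments. Mitochondrial rows held 22.3% of the counts in wt cytoplasm, 15.9% in wt total, 11.8% in Mkrn3ox cytoplasm and 9.94% in Mkrn3ox total RNA, and 0.136% to 1.2% in the RIP groups. Rn7sk, a small nuclear RNA with no poly(A) tail, held 1.08% of the GFP input and 1.14% of the GFP-Mkrn3 input, and 0.124% and 0.0748% of the IPs, while the fractionation groups held 0%. Genes of replication histones held 0.417% and 0.432% of the inputs, 0.232% and 0.199% of the IPs and 0.0173% to 0.0481% of the fractionation groups. Genes that overlap another gene held 47.8% of the protein-coding counts in the fractionation table and 16.2% in the RIP inputs.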
